A study of Populus tremula x Populus alba with 24 samples.

How the data were processed

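RNA sequencing was used to follow poplar roots after treatment with lipochitooligosaccharides (LCO), signal molecules that rhizobia and some fungi release towards plant roots. Per the labels' protocols, roots were immersed for 1 h, starting 3 h after dawn, in a 10 nM solution of LCO from the bacterium Rhizobium sp. IRBG74 or in a control solution with 0.005% ethanol. Treated roots were collected at 15 min, 30 min, 1 h, 2 h, 4 h, 8 h and 24 h, and the control at time 0. The labels do not state plainly whether the control roots were immersed, nor whether the times run from the start or the end of the immersion. Each library is a pool of roots from 4 plants, and the labels call the pools of a group biological replicates. The labels describe 24 samples, and 22 of them have a column in the tables used here. Replicate 2 of 30 min and replicate 3 of 2 h were not analysed here, which leaves 2 libraries in each of these groups and 3 in each of the others.

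The deposited gene and transcript tables hold the natural log of (TPM + 1), quantile-normalized across the libraries by the authors, as the names given to the tables and the values show. TPM, a relative transcript abundance, corrects a read total for transcript length and library total. The base of the log was settled from the values: back-transformed with base e, the libraries sum to 936253 to 936552 TPM, against 204126 to 204330 with base 2 and a far higher total with base 10. Kallisto, which estimates transcript abundance without a full alignment, and sleuth, which tests such estimates, are named in the submitters' processing notes, with no version or role. The genome build is not given in the sources used here. Transcript identifiers carry the suffix v3.1 and genes have Potri identifiers, which name genes of Populus trichocarpa. The samples are of Populus tremula x Populus alba, and how the difference in species affects the values was not examined. Quantile normalization gives every library nearly the same set of values, so a change in the total output of the roots, or in the spread of all genes, is removed before any test. TPM keeps no depth: the read number behind each value is unknown, no counting interval can be given, and a value listed at 0 is not shown to be an absence of transcript.

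Values were back-transformed to TPM and taken as log2(TPM + 1). The pseudocount of 1 TPM makes fold changes of genes with low values smaller than the ratio of their TPM. Genes with a mean of at least 1 TPM over the 22 libraries were tested, which left 25636 of 42950 genes and 29885 of 63498 transcripts. The tables were normalized separately and were tested separately. A linear model with 1 mean per group was fitted to all 22 libraries in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and a mean-variance trend, so that the groups share 1 estimate of the spread with 14 residual degrees of freedom. Each time was compared with the control, two-sided, and a moderated F test over the 7 comparisons asked whether a gene differed at any time. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Means are given as TPM ± SD over libraries. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

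The design, the tests, the alternatives other than those named as added, and the rule for naming genes were fixed before the data were examined. The design had assumed 24 libraries and 16 residual degrees of freedom, and TPM rather than its log. The gene lists fixed at that point were defined by gene descriptions. No annotation was used here, so the lists are void, the planned test of gene lists was not run, and genes go by identifier. The rule then names at most 2 genes that rose and 2 that fell at each time: the largest log2 fold changes among called genes with a mean of at least 5 TPM whose libraries all lie on 1 side of all control libraries. Positions on chromosomes and gene functions are therefore not given. Reads that fit near-identical gene copies, or several transcripts of a gene, are shared out by an estimate, and which genes this touches was not examined.

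The procedure was tested on simulated data over 25636 genes, of which 200 were changed, 50 at each fold. The noise was normal and independent between genes, with 1 spread per gene for all groups and no library standing apart. In the data the 15 min and 30 min libraries vary more (median SD 0.319 and 0.303 on the log2 scale, against 0.173 at 8 h). The numbers may therefore be too favourable for these 2 times. For 15 min against control, 5 of the 50 genes changed 1.5-fold were called, 21 of those changed 2-fold, 44 of those changed 4-fold and 46 of those changed 8-fold, with 7 false calls. For 30 min, with 2 libraries, the numbers were 0, 19, 40 and 46, with 8 false calls. Overlaps between times were set beside 100 draws in which unchanged groups shared the same 3 controls; residuals were drawn without replacement, a change made after a first version with replacement had been run. The alternatives covered the pseudocount, the filter, a block for the replicate number, the variance trend, median-centring, the libraries in the fit and leaving out each library. Added after seeing the data were the number of genes listed at 0 as a covariate, 15 min replicate 2 and 30 min replicate 3 left out together, a quality weight for each library, leaving out each library of the groups not compared, the division of the controls between the times of a pair, and recounts of the genes lower or higher at all times and of the overlap of 15 min with the late times.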

Results

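The data are gene and transcript levels in poplar roots at time 0 (control, n = 3) and at 15 min (n = 3), 30 min (n = 2), 1 h (n = 3), 2 h (n = 2), 4 h (n = 3), 8 h (n = 3) and 24 h (n = 3) after LCO. Each library is a pool of roots from 4 plants. The time course asks which root genes change after the signal, and when. Control roots were collected at time 0 only, so each comparison combines LCO with the time since immersion and, other than at 24 h, with the time of day. The labels do not say plainly whether the control roots were immersed in the control solution; if they were not, each comparison also contains immersion itself. The read depth of the libraries is unknown. Genes listed at 0 numbered from 9029 in 24 h replicate 1 to 13313 in 30 min replicate 3, out of 42950. Correlations between libraries of a group, across genes, ranged from 0.881 to 0.979.

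Of 25636 genes tested, 15091 (58.9%) differed between the control and at least 1 time in the limma F test, and 13096 were called at 1 or more single times. The number of genes called against control was 2066 at 15 min, 456 at 30 min, 739 at 1 h, 1073 at 2 h, 2452 at 4 h, 9294 at 8 h and 9189 at 24 h. Among the genes called by the F test, the largest difference from control lay at 24 h for 4973 and at 8 h for 4672. It lay at 15 min for 1547, 30 min for 1409, 1 h for 573, 2 h for 1153 and 4 h for 764. The time of the largest difference need not be a time at which the gene was called, as 3380 of these genes were called at no single time. The median log2 fold change over all tested genes lay between -0.02 at 30 min and 0.05 at 24 h. The first principal component, with 42.8% of the variance, placed the 8 h and 24 h libraries between 80.5 and 96.0 and the control libraries between -31.7 and -26.7. On this axis 15 min replicate 2 lay at -75.3, and replicates 1 and 3 lay at 17.2 and 9.91.

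**Figure D1:**
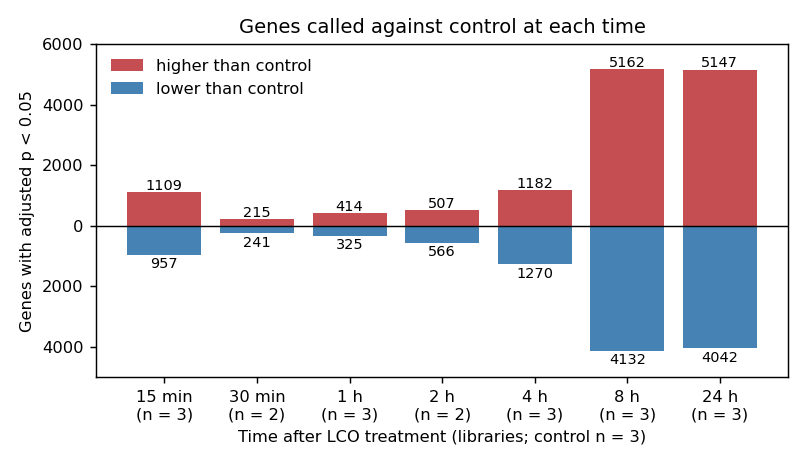
Genes called against control at each time (adjusted p under 0.05, limma), with genes higher than control drawn upward and genes lower than control drawn downward from 0; the number of libraries stands under each time. The bars are tallest at 8 h (5162 higher, 4132 lower) and 24 h (5147 higher, 4042 lower) and shortest at 30 min (215 higher, 241 lower).

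**Figure D2:**
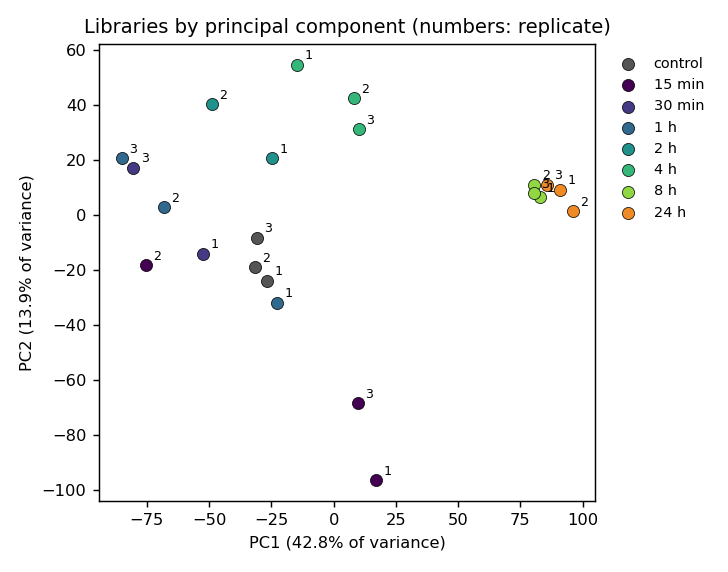
Each point is 1 library, placed by its first (x, 42.8% of variance) and second (y, 13.9%) principal component, coloured by group and numbered by replicate. The 8 h and 24 h libraries lie together at the right, and 15 min replicate 2 lies apart from 15 min replicates 1 and 3.

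At 15 min, the earliest time, 2 genes that were abundant in control roots had dropped to a few TPM. Potri.008G062300 stood at 1034 ± 90.8 TPM in the control (SD, n = 3) and at 8.54 ± 6.92 TPM at 15 min (n = 3), a log2 fold change of -6.99 (SE 0.36, adjusted p = 2.51e-09). Potri.010G195700 fell from 471 ± 129 to 4.81 ± 3.15 TPM, a log2 fold change of -6.44 (adjusted p = 1.56e-09). Among genes that rose, Potri.006G105500 went from 4.94 ± 2.36 to 50.4 ± 8.55 TPM, a log2 fold change of 3.19 (adjusted p = 1.61e-05). Potri.002G007000 rose from 0.519 ± 0.0792 to 9.79 ± 2.64 TPM (2.80, adjusted p = 2.91e-06). In all, 1109 genes were higher and 957 lower than control, of which 548 and 395 differed at least 2-fold. The count rested on single libraries: it was 5831 without 15 min replicate 2, 848 without replicate 1, 1068 without replicate 3, 856 without control replicate 1 and 1302 without control replicate 2. With only the 6 libraries of both groups in the fit it was 240, with library weights 9491 and without both 15 min replicate 2 and 30 min replicate 3 6761.

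At 30 min, Potri.008G062300 (10.3 ± 1.91 TPM, n = 2, log2 fold change -6.53, adjusted p = 3.43e-08) and Potri.010G195700 (5.17 ± 2.50 TPM, -6.28, adjusted p = 1.57e-08) were still far below their control levels. Potri.002G007000 stood at 10.7 ± 0.694 TPM against 0.519 ± 0.0792 in the control, a log2 fold change of 2.95 (adjusted p = 9.06e-06). Potri.001G065500 also passed the threshold (adjusted p = 0.0447), with 7.66 and 161.8 TPM in the 2 libraries and 0, 0 and 6.07 TPM in the controls; without 30 min replicate 3 its adjusted p was 0.671. Of the 456 genes called, 215 were higher and 241 lower, and 154 and 179 of these differed at least 2-fold. The 2 libraries decide this count: it was 4501 without replicate 1 and 83 without replicate 3, each with 1 library that is assumed to vary like the other groups, and 129, 258 and 251 without control replicates 1, 2 and 3. A block for the replicate number gave a count of 761. Libraries of other groups enter through the shared spread, and the count was 780 without 15 min replicate 2 and 301 without 24 h replicate 2. It was 37 with only the 5 libraries of both groups, 164 with genes at 0 as a covariate, 78 with library weights and 111 without both 15 min replicate 2 and 30 min replicate 3.

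At 1 h, Potri.009G106000 had risen from 5.72 ± 1.87 to 85.0 ± 20.1 TPM (n = 3), a log2 fold change of 3.68 (SE 0.47, adjusted p = 0.000173). Potri.019G097750 was listed at 55.0, 26.1 and 31.6 TPM, against 0, 0 and 3.80 TPM in the controls (adjusted p = 0.000438), and at 0 in every library of 30 min, 2 h and 8 h. Potri.008G062300 (11.1 ± 1.44 TPM, log2 fold change -6.42, adjusted p = 6.96e-09) and Potri.010G195700 (5.61 ± 0.953 TPM, -6.13, adjusted p = 3.62e-09) remained low. Of 739 genes called, 414 were higher and 325 lower. The count was 330 without control replicate 1, 425 without control replicate 3, 461 without 1 h replicate 2 and 461 without 1 h replicate 3. It was 234 with only the 6 libraries of both groups, 457 with genes at 0 as a covariate, 4988 with library weights and 1370 without both 15 min replicate 2 and 30 min replicate 3.

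At 2 h, Potri.014G143200 reached 97.7 ± 4.82 TPM (n = 2) from 10.7 ± 4.33 TPM in the control (n = 3), a log2 fold change of 3.15 (SE 0.36, adjusted p = 3.26e-05); at 15 min it had been at 10.6 ± 0.805 TPM. Potri.014G095000 was called higher (adjusted p = 0.00615) at 5.19 and 36.4 TPM, against 0, 1.03 and 0 TPM in the controls, and its adjusted p was 0.167 without 2 h replicate 2. Potri.008G062300 had gone down to 5.34 ± 2.43 TPM (log2 fold change -7.40, adjusted p = 6.25e-09) and Potri.010G195700 to 2.71 ± 0.529 TPM (-6.96, adjusted p = 2.77e-09). There were 507 genes higher and 566 lower than control, 1073 in all. The count was 346 without 2 h replicate 1, 474 without 2 h replicate 2 and 590 without control replicate 1, and 639 with only the 5 libraries of both groups. Library weights gave 2113, and 1706 were called without 15 min replicate 2 and 30 min replicate 3.

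At 4 h, Potri.006G223900, at 3018 ± 984 TPM in the control, had dropped to 23.0 ± 7.25 TPM (n = 3), a log2 fold change of -6.97 (adjusted p = 6.23e-10); it had already been called lower at 15 min, at 67.5 ± 25.4 TPM. Potri.008G062300 stood at 3.80 ± 0.938 TPM (-7.77, adjusted p = 2.82e-10). Potri.009G106000 remained high at 63.7 ± 9.89 TPM (3.29, adjusted p = 0.000189). Potri.003G061200 was listed at 92.9, 45.9 and 34.3 TPM against 0, 0 and 16.8 TPM in the controls (adjusted p = 0.0130), and lost its call without control replicate 1 (0.0792), control replicate 2 (0.0699) or 4 h replicate 1 (0.0625). Of 2452 genes called, 1182 were higher and 1270 lower, and 467 and 770 of these differed at least 2-fold. The count was 1460 without control replicate 1, 1586 without 4 h replicate 1 and 1352 without 4 h replicate 2, and 6376 with library weights.

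At 8 h, Potri.008G062300 was at 2.28 ± 0.904 TPM (n = 3), its lowest mean of the time course, with a log2 fold change of -8.33 (SE 0.36, adjusted p = 9.21e-11), and Potri.006G223900 was at 10.4 ± 3.41 TPM (-8.04, adjusted p = 9.21e-11). Potri.007G112900 was listed at 0 in all 3 controls and at 46.0, 39.8 and 55.4 TPM at 8 h (adjusted p = 0.00114). Potri.017G047932 rose from 8.04 ± 5.01 to 138 ± 22.3 TPM (4.12, SE 1.40, adjusted p = 0.0291); it lost its call in 7 of 16 alternatives, with adjusted p values from 7.49e-05 to 0.161 over all of them. These 2 genes also stood at 64.1 and 91.9 TPM in 15 min replicate 1 and at 34.9 and 53.0 TPM in replicate 3, while 15 min replicate 2 had both at 0. Of 9294 genes called (36.3% of those tested), 5162 were higher and 4132 lower, and 1820 and 2116 of these differed at least 2-fold. Leaving out any single library of the control or 8 h gave 6692 to 8290 genes, and library weights gave 14343.

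At 24 h, when the time of day was again that of the control, Potri.008G062300 (3.35 ± 1.24 TPM, n = 3, log2 fold change -7.93, adjusted p = 1.47e-10) and Potri.006G223900 (13.2 ± 3.35 TPM, -7.70, adjusted p = 1.47e-10) were still far below their control levels. Potri.007G112900 was listed at 58.0, 106 and 58.7 TPM, against 0 in all 3 controls (adjusted p = 0.000497). Potri.011G080100 was at 259, 251 and 169 TPM, against 39.4, 3.57 and 3.47 TPM in the controls (log2 fold change 4.57, SE 1.14, adjusted p = 0.00512), and missed the threshold with a pseudocount of 0.1 (0.0516; range over its alternatives 9.45e-05 to 0.0516). It was also at 137 and 77.2 TPM in 15 min replicates 1 and 3 and at 17.1 TPM in replicate 2. There were 5147 genes higher and 4042 lower than control, and 1862 and 2195 of these differed at least 2-fold.

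**Figure D3:**
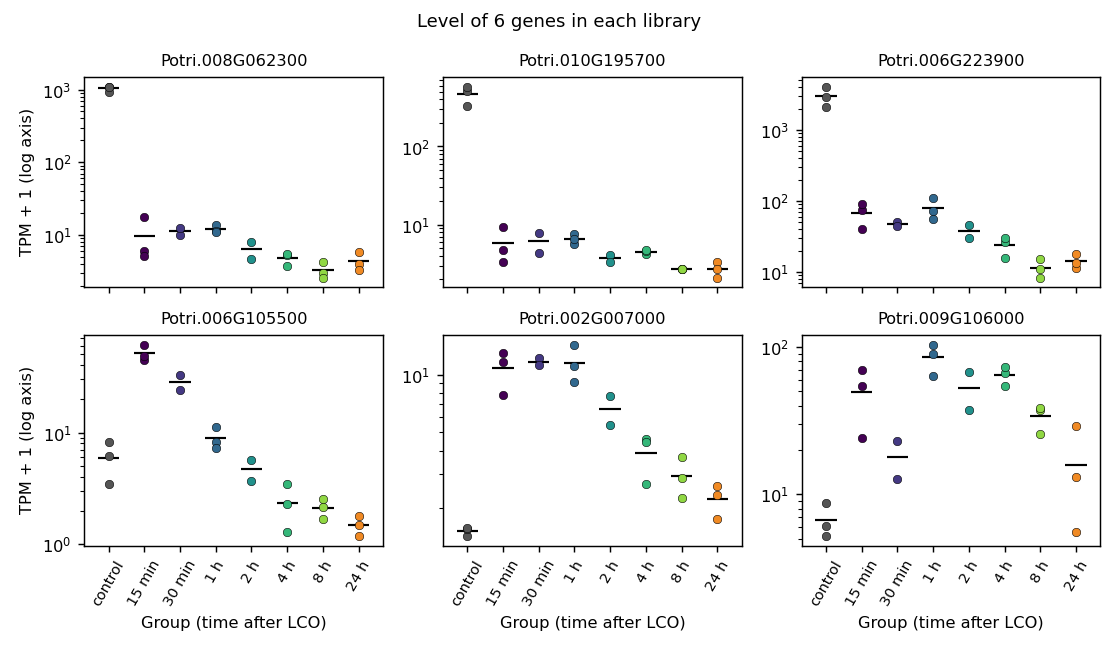
TPM + 1 (log axis) of 6 genes in every library, by group. Points are libraries and bars are group means of TPM, plus 1. Potri.008G062300, Potri.010G195700 and Potri.006G223900 lie below all 3 controls in all 19 treated libraries, and Potri.006G105500 is at 50.4 TPM at 15 min and 0.493 TPM at 24 h.

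Potri.008G062300, Potri.010G195700 and Potri.006G223900 belong to 83 genes called lower than control at all 7 times. Their median level in the control was 46.4 TPM, 31 of them were above 100 TPM there, and 13 were at least 10-fold lower at 15 min. The median log2 fold change of the 83 genes was -1.89 at 15 min and -2.32 at 24 h. The number was 51 without 30 min replicate 3, 52 with library weights and 26 when each time was fitted with only its own libraries and the controls, all 26 of them among the 83. In the other direction, 4 genes were called higher at all 7 times, with log2 fold changes from 0.52 to 2.53; this number was 0 without 2 h replicate 1, 4 h replicate 2 or 8 h replicate 2, 11 without 30 min replicate 1, and between 0 and 11 in all alternatives. At 5 or more times, 202 genes were called lower and 69 higher. Of 7899 genes called at 2 or more times, 7205 were called in 1 direction and 694 in both.

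The 8 h and 24 h changes were compared next. Of the 9294 genes called at 8 h, 6692 (72.0%) were called in the same direction at 24 h, 3772 of them higher and 2920 lower, where independent lists would share 1036 and 651. The direct comparison of 24 h with 8 h called 679 genes, 315 higher and 364 lower at 24 h. Across genes, which are not independent replicates, the fold changes at both times had r = 0.885, against a median of 0.517 (0.0537 to 0.816, percentiles 2.5 to 97.5) for unchanged groups that share the controls. Their covariance was 0.628 against 0.0507 in that simulation, a difference of 0.577. With 1 control library used for 1 of these times and the other 2 for the other, in each of the 6 ways, r was 0.727 to 0.798 and the covariance 0.559 to 0.605. The counts of shared calls given here use the same 3 controls for both times, and part of their excess may come from that. Of the 2452 genes called at 4 h, 1968 (80.3%) were called in the same direction at 8 h. Their fold changes had r = 0.642, inside the range for unchanged groups (median 0.523, -0.140 to 0.816), and a covariance of 0.295 against 0.0513; with divided controls r was 0.437 to 0.554 and the covariance 0.227 to 0.272.

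The 15 min changes were set beside the late ones in the same way. Of 2066 genes called at 15 min, 737 (35.7%) were called in the same direction at 8 h and 662 (32.0%) at 24 h. At 24 h, 454 genes were lower at both times, where independent lists would share 151, and 208 were higher at both, where they would share 223. In the opposite direction, 384 genes were higher at 15 min and lower at 24 h, Potri.006G105500 among them, and 46 were lower and then higher. The numbers that independent lists would share in opposite directions were not computed. The covariance of the fold changes at 15 min and 24 h was 0.161 against 0.0523 in the simulation, with r = 0.346 against a median of 0.483 (-0.0713 to 0.837); with divided controls r was 0.182 to 0.277 and the covariance 0.0989 to 0.137. The overlap depended on which 15 min libraries were used. Without replicate 2, 5831 genes were called at 15 min, of which 3078 (52.8%) were called in the same direction at 8 h and 2896 (49.7%) at 24 h, with 1470 higher and 1426 lower at both 15 min and 24 h, where independent lists would share 695 and 489. Without replicate 1 the shares were 31.5% and 28.3%, and without replicate 3 28.6% and 26.6%. Over the genes called the same way at 8 h and 24 h, 15 min replicates 1 and 3 lay at median positions of 0.401 and 0.398 between the control (0) and these late times (1), and replicate 2 lay at -0.0712.

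In the transcript table, 15028 of 29885 transcripts tested differed between the control and at least 1 time in the F test; with transcripts at 0 as a covariate the number was 7951. Of 3792 genes with 2 or more tested transcripts, 181 had 1 transcript called higher and another called lower at 8 h, and 207 at 24 h. Such a pair needs 2 called transcripts, which 370 genes had at 8 h and 391 at 24 h. At 8 h, transcript 1 of Potri.010G084100 rose from 0.169 ± 0.147 to 6.09 ± 1.18 TPM (log2 fold change 2.59, adjusted p = 0.000156), while transcript 7 fell from 5.14 ± 1.15 to 0.0299 ± 0.0518 TPM (-2.56, adjusted p = 0.000367); the gene as a whole was not called (0.24, adjusted p = 0.365). At 24 h, transcript 3 of Potri.009G120000 rose from 1.21 ± 1.92 to 21.9 ± 2.02 TPM (3.70, adjusted p = 0.000157) and transcript 5 fell from 16.7 ± 1.71 to 0.741 ± 1.27 TPM (-3.57, adjusted p = 0.000369), with a gene-level log2 fold change of 0.37 (adjusted p = 0.0379). Reads common to transcripts of a gene are divided between them by an estimate, and the error of that division is not in these values.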

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

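1 named gene, Potri.006G105500, was called higher than control at 15 min (log2 fold change 3.19) and lower at 24 h (-1.93). Its level went from 4.94 ± 2.36 TPM in the control to 50.4 ± 8.55 TPM at 15 min, 27.4 ± 5.96 TPM at 30 min and 7.93 ± 2.12 TPM at 1 h, and to 0.493 ± 0.305 TPM at 24 h. The log2 level at 24 h minus that at 15 min was -5.11 (SE 0.34, limma, adjusted p = 5.15e-09), which follows from the opposite calls against the same controls and adds no separate evidence. Against control it was called higher at 15 min and 30 min and lower at 4 h, 8 h and 24 h. No explanation was tested for this gene.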

How the results depend on the processing

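The weights, the covariate, the joint leaving out of 2 libraries and leaving out libraries of groups not compared were chosen after seeing the data. Counts are of genes called unless transcripts are named, and for counts that moved over 1.5 times the cause was not tested. With only the libraries of both groups in the fit, 240 were called at 15 min, 37 at 30 min, 234 at 1 h and 639 at 2 h. More were called at 4 h (3129), 8 h (11515) and 24 h (10765). This fit has fewer degrees of freedom and takes the spread from these libraries alone. The main fit shares 1 spread, though the median SD within groups differed. It was 0.319, 0.303, 0.272, 0.185, 0.173, 0.173 and 0.196 from 15 min to 24 h, and 0.205 in the control (log2 scale). Library weights gave 9491 at 15 min, 78 at 30 min, 4988 at 1 h, 2113 at 2 h, 6376 at 4 h and 14343 at 8 h; they come from a gene-by-gene estimator, chosen after a likelihood-based one had given a convergence warning and its counts had been seen. Genes (or transcripts) at 0 as a covariate gave 164 at 30 min, 457 at 1 h and 7951 transcripts in the F test. Without both 15 min replicate 2 and 30 min replicate 3, 6761 were called at 15 min, 111 at 30 min, 1370 at 1 h and 1706 at 2 h.

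Leaving out 1 library at a time, of the control or the time compared for the counts by time and any of the 22 for the F tests, gave 848 to 5831 at 15 min, 83 to 4501 at 30 min, 330 to 953 at 1 h, 346 to 849 at 2 h, 1352 to 1867 at 4 h, 6692 to 8290 at 8 h, 6873 to 7984 at 24 h, 13342 to 17573 in the gene F test and 12672 to 17709 transcripts. Libraries of other groups share the spread: leaving out 1 of these gave 301 to 780 at 30 min and stayed within 1.5 times at the other 6 times, with the highest counts without 15 min replicate 2 (995 at 1 h, 1392 at 2 h, 3013 at 4 h, 10436 at 8 h, 10348 at 24 h) or, at 15 min, 30 min replicate 1 (2538). For the counts by time and the F tests, all other settings but the block stayed within 1.5 times. The pseudocount, both filters, the trend and median-centring were among these settings. The number of genes called higher at every time moved further, from 4 to 8 with a pseudocount of 0.1 and to 2 with no filter on low values. It was 3 with the stricter filter, 3 with no trend and 4 with median-centring. With the replicate number as a block, 761 genes were called at 30 min against 456, and no other count moved over 1.5 times. Whether the numbers pair the samples is not settled. Of 70 same-numbered pairs, 23 had deviations correlated over 0.1 (range -0.355 to 0.386, median 0.048). In other groups, 12 of 22 libraries were closest to a library of their own number, so an effect shared by a replicate number is not excluded.

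For the 28 gene and time pairs named, 419 of 440 checks kept the call and its direction, 21 lost the call and 0 reversed. The calls lost were those of Potri.001G065500 (8 of 15), Potri.017G047932 (7 of 16), Potri.003G061200 (3 of 16), Potri.014G095000 (2 of 15) and Potri.011G080100 (1 of 16). The planned gene list tests and their alternatives were not run. Depth is unknown and limits what can be said of genes at low TPM.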

Other observations

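Tests of time of day and of a shared factor for the 8 h and 24 h genes, the tests of 1 control library and of decay for the genes lower at all times, and the relation of genes at 0 to the first principal component were chosen only after the results had been seen.

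Genes with neighbouring identifiers were called in the same direction more often than in permuted orders. At 4 h there were 167 such pairs against a mean of 75.8 and a highest value of 104 over 1000 permuted orders, and at 2 h 46 against 14.8 and 33. The ratio to the mean was smallest where most pairs were called, 1.30 at 8 h (1449 against 1112) and 1.33 at 24 h (against a mean of 1085), and highest at 30 min (3.87, from 10 pairs). At 6 of the 7 times the pairs exceeded every permuted order, and at 30 min the highest permuted order equalled the 10 pairs observed. The permutation p was 0.002 at 30 min and 0.001 at each of the other times, so an excess over permuted orders was seen at all 7. The rule written beforehand asked that all 7 exceed every permuted order. It was missed by the tie at 30 min, and by that rule the hypothesis that neighbouring genes change together stays undecided. Sharing of reads between near-identical neighbouring copies was not tested, as no sequence was used here.

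The first pattern is that 15 min replicate 2 stood apart from replicates 1 and 3. Fewer genes detected in it (12139 listed at 0, against 9241 and 9265) is argued against as the whole cause: over genes with a mean of at least 20 TPM its differences from the other replicates were 1.90 times those between them. That it holds roots of a later time cannot be told apart from other causes. Its median position was 0.909 between 15 min replicates 1 and 3 (0) and 30 min and 1 h (1), which met the bound of 0.75 written for a later time. The bound was judged wrong after this value was seen, because the controls, at time 0, lay at 0.754 to 0.795 and the 8 h and 24 h libraries at 0.160 to 0.271, so the axis does not order libraries by time; replicates 1 and 3 may as well be the unusual ones.

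The second pattern is the number of genes called at 8 h and 24 h. Values listed at 0 are argued against as the whole cause: of genes with a mean of at least 20 TPM, 42.7% were called at 24 h, against 35.8% of all tested. Library quality or depth, of which the number at 0 may be a sign, is not covered by this test. With genes at 0 as a covariate, 8867 genes were called at 8 h against 9294, and 7671 at 24 h against 9189. The gene F test then called 10600 against 15091. Time of day as the whole cause is argued against by the 72.0% of 8 h calls called the same way at 24 h, where the bound was 50%. That share uses the same controls for both times. With divided controls it was 31.5% to 79.4%. Where 24 h was set against 1 control library it was 49.97%, 37.5% and 31.5%, short of the bound, with fewer genes called at 24 h. The covariance of the fold changes stayed at 0.559 to 0.605 in all divisions. A factor that 15 min replicates 1 and 3 share with the late libraries, which no label names, cannot be told apart from LCO or time since immersion. Genes listed at 0 numbered 9241 and 9265 in these 2 replicates and 9029 to 10070 at 8 h and 24 h. They numbered 12139 in 15 min replicate 2, 10314 to 10663 in the controls and 10016 to 10762 at 4 h. Against 15 min without replicate 2, 45.4% of the 6692 shared calls remained at 8 h and 46.5% at 24 h, between the bounds of 10% and 50%; on the axis from control (0) to the late libraries (1), 15 min replicates 1 and 3 lay at 0.401 and 0.398, replicate 2 at -0.0712 and 4 h at 0.356 to 0.464, positions for which no bound had been set.

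The third pattern is the 83 genes lower at all 7 times. A single unusual control library is argued against as the whole cause: without control replicates 1, 2 and 3 in turn, 58, 73 and 64 of the 83 were still called lower at all times. For all 83 genes every control library lay above every treated library. Leaving out 1 control could therefore lose calls but not reverse a gene. Time of day is argued against only as the whole cause: 83 of the 88 genes lower at the 6 earlier times were also lower at 24 h. This test had little room to come out otherwise. The 88 genes were picked as already lower at 15 min, and the 24 h comparison uses the same control libraries. Decay after a complete stop of transcription at time 0 that lasted is argued against as the whole cause. The median log2 fold change was -1.89 at 15 min, -1.82 at 1 h and -2.32 at 24 h. At 24 h, where such decay leaves almost nothing, the median level was 7.24 TPM, 3.02 on the log2 scale above the prediction. With almost nothing predicted, this excess is in effect the observed level itself, so it does not cover a stop that was only partial. On the slower clock from the start of immersion the excess was 0.90 at 1 h (quartiles 0.54 and 1.21), while at 30 min it was 0.11 (quartiles -0.04 and 0.52), a time that does not argue against decay. A partial or temporary stop, with half-lives by the level at 15 min as short as 2.15 min (median 7.92 min) from time 0, or 10.7 min (median 39.6 min) from the start of immersion, cannot be told apart from other causes, since no measured half-lives were used here; immersion or handling is also confounded with the groups, as the labels do not say plainly whether control roots were immersed, and LCO itself stays open.

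The 6 libraries of a comparison of 3 with 3 make 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real split called 2066 genes at 15 min and the highest other 5, 739 against 0 at 1 h, 2452 against 1 at 4 h, 9294 against 1 at 8 h and 9189 against 1 at 24 h. Each other split mixes control and treated libraries on both sides, which puts any difference between the groups into the spread. Their low counts are therefore not a level for chance, and no conclusion is drawn from them. For the F tests, group labels unrelated to the levels are argued against: of 100 groupings, the real 1 included, only the real 1 gave as many. It called 15091 genes against at most 4353 in the others, and 15028 transcripts against at most 6162. These other groupings also mix the groups and put their differences into the spread, so their counts are no level for chance either. The cause of the differences is not addressed. Within groups, the position of the 22 libraries on the first principal component and their number of genes at 0 had r = -0.739 (permutation p = 0.0596) and rho = -0.632 (permutation p = 0.0358), with r = -0.587 without the 2 farthest libraries.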
